A study of Mus musculus with 12 samples.

How the data were processed

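Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in mouse bone marrow-derived macrophages (BMDMs) that were wild type (WT) or knocked out (KO) for Baf60a. Baf60a, encoded by Smarcd1, is a subunit of the SWI/SNF chromatin remodelling complex. Cells were left untreated or given oxidised LDL (oxLDL, 50 µg/ml for 48 h), the modified lipoprotein that loads macrophages with cholesterol. The 12 libraries form 8 groups in 2 cohorts. The cohort called the first cohort here holds 1 library per group, made with the Omni-ATAC protocol, and its labels do not give the ApoE status. The ApoE KO cohort holds 2 libraries per group, made from cryopreserved cells on an ApoE KO background with a Nextera kit. Its genotype labels give a floxed Baf60a with Lyz2-Cre in KO and without it in WT. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

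Reads were paired-end with a length of 150, per the labels' protocols. The tools were FastQC, Trim Galore, cutadapt, Bowtie2 2.3.4.1, Picard, SAMtools 1.2, bedtools 2.28.0 and MACS3 for the first cohort or MACS2 for the ApoE KO cohort on genome build mm10, per the submitters' processing notes. The role and parameters of each step, including any shift of reads for the transposase, removal of duplicates or filter on repeats, are not given in the sources used here. The deposited files hold 1 peak list per library, so peaks were called per sample and not on pooled samples. In both cohorts each peak has a caller score made by the authors, a whole number of at least 13. The lists of the ApoE KO cohort also hold, as deposited by the authors, a fold enrichment and the -log10 of a p and of a q for each peak. In these lists the deposited score was 10 times the -log10 q rounded down for all but at most 11 peaks of a library. These values belong to single peaks and were used to rank and filter peaks within a list. The ApoE KO lists cover the 19 autosomes, and the first cohort lists also cover X and Y. No list holds reads, so sequencing depth is unknown and no interval that needs it is given. Differences in depth move the number of peaks called.

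Peak numbers, shares and gene neighbourhoods were compared within a cohort, and calls at single loci were also set side by side across cohorts. For gene-boundary shares of peaks and for gene neighbourhoods, lists of equal length were used. They hold the peaks with the highest score, as many as in the shortest list of the cohort. That was 82177 in the first cohort and 24397 in the ApoE KO cohort. Region counts and the overlap within minus between conditions used full lists, with lists of equal length as an alternative. Gene positions came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 20665 autosomal protein-coding genes. It gives gene start and end without strand, and no genome sequence was used here. The planned share of peaks near a transcription start therefore became the percent of autosomal peaks whose summit (or centre, in the first cohort) lies within 1 kb of either boundary of a gene, called the gene-boundary share. The planned gene neighbourhood became the gene with 50 kb on each side, on autosomes. Motifs were not analysed here.

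Peak number (log2) and gene-boundary share were tested with an exact permutation test, two-sided, that exchanged genotype labels within cohort and treatment, or treatment labels within cohort and genotype. This gives 144 arrangements and a smallest p of 0.0139. For regions, all peaks were merged into 147937 regions where they overlapped by 1 bp or more, and a region counted as called in a library that had a peak in it. Regions called in 6 of 6 libraries of one condition and 0 of 6 of the other were counted, and, since fewer than 10 passed, also those called in at least 5 against at most 1. For these regions, the distance to a gene, and whether a region lies inside one, were taken at the region's centre. Overlap of peak sets was measured with the Jaccard index of covered base pairs. Peaks per gene neighbourhood in equal-length lists were tested with limma 3.58.1 in R 4.3.3 on log2(peaks + 0.5) for 16692 genes with a mean of at least 1 peak, with genotype-by-treatment groups and cohort in 1 model and Benjamini-Hochberg adjustment. Fold changes on this scale are those of peaks + 0.5. The 24 gene lists, with 564 genes of which 544 matched on autosomes, were tested with limma's camera at a preset correlation of 0.01 and with an estimated one. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

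The tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. The rule named Smarcd1, Lyz2, Apoe and Nrf1 in any case, the genes with the smallest limma p (5 per direction where none passed, with ties), and the 5 regions of each separated set with the highest mean score percentile, with the nearest gene. Other genes named are said to have been chosen after their values were seen. The alternatives were a stricter threshold (a -log10 q of at least 5, or, in the first cohort, the upper 50% of each list by score, which cannot change a ratio of list lengths there), covered base pairs, other list lengths and windows, 50% coverage of a region, another pseudocount, no filter, the ApoE KO cohort alone, each library left out, and replicate number as a block. Marks in the file names that read like lanes were also examined, though whether they are sequencing lanes is not given in the sources used here. In the ApoE KO cohort both WT untreated libraries and 1 KO oxLDL library carry L001 and the other 5 carry L003. Untreated WT and KO therefore differ in this mark throughout, and so do untreated and oxLDL-treated WT.

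Scripts were tested on simulated data. With genes changed for the genotype comparison over both treatments (16566 genes), the limma step recovered 13% of genes changed 2-fold and 78% of those changed 4-fold, with 1 false call. The simulated counts were independent Poisson draws around cohort means. In the data neighbouring genes share peaks and 288 genes had no residual spread, so these rates need not hold there. The permutation test gave p of at most 0.05 in 3.5% of 200 simulated sets without an effect and in 84% of sets with an effect of 2 SD. The count of separated regions found 54 in KO where 50 were planted and 36 in WT where 30 were planted, so it also counts regions that separate without a planted effect.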

Results

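ATAC-seq peak lists of 12 BMDM libraries were compared between Baf60a KO and WT cells, untreated or given oxLDL, to ask how loss of this SWI/SNF subunit and lipid loading change chromatin accessibility. The first cohort had 1 library in each of 4 groups and the ApoE KO cohort had 2 in each of 4 groups. First-cohort lists held 82177 to 141441 peaks and covered 43.0 to 77.9 Mb, and ApoE KO lists held 24397 to 44524 peaks and covered 11.3 to 25.3 Mb. Peak numbers, shares and gene neighbourhoods were therefore compared within cohorts, and where calls at a locus are set side by side across cohorts the lists differ this much in length. Of the 147937 merged regions, 17343 (11.7%) were called in all 12 libraries.

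The targeted gene, Smarcd1, was examined first. A region over its start boundary (mm10, chromosome 15, 99701894 to 99702982) was called in 12 of 12 libraries, KO and WT alike. A region inside the gene (chromosome 15, 99705573 to 99705960) was called in all 4 first-cohort libraries, 2 KO and 2 WT, and in 0 of 8 ApoE KO libraries. The deleted exons are not given in the labels, so these peaks do not check the genotype. Lyz2, the lysozyme gene of macrophages whose locus drives Cre in the ApoE KO cohort, had a region over its end boundary (chromosome 10, 117281468 to 117282491) in 12 of 12 libraries. Nrf1, a transcription factor of mitochondrial genes, had one over its start boundary (chromosome 6, 30047197 to 30048883) in 12 of 12.

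Apoe, the apolipoprotein gene knocked out in the ApoE KO cohort, differed between the cohorts. A region over the lower boundary of the gene (chromosome 7, 19696100 to 19697076) and a region inside the neighbouring Tomm40 (chromosome 7, 19702279 to 19703473) were each called in 8 of 8 ApoE KO libraries and in 0 of 4 first-cohort libraries. A region inside Apoe (chromosome 7, 19698859 to 19700017) was called in 4 of 4 first-cohort and 3 of 8 ApoE KO libraries. Fewer calls in the shorter ApoE KO lists were common. Of the 70918 regions called in all 4 first-cohort libraries, 24.5% were called in all 8 ApoE KO libraries. Neither of the first 2 regions differed in calls between Baf60a genotypes.

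**Figure D1:**
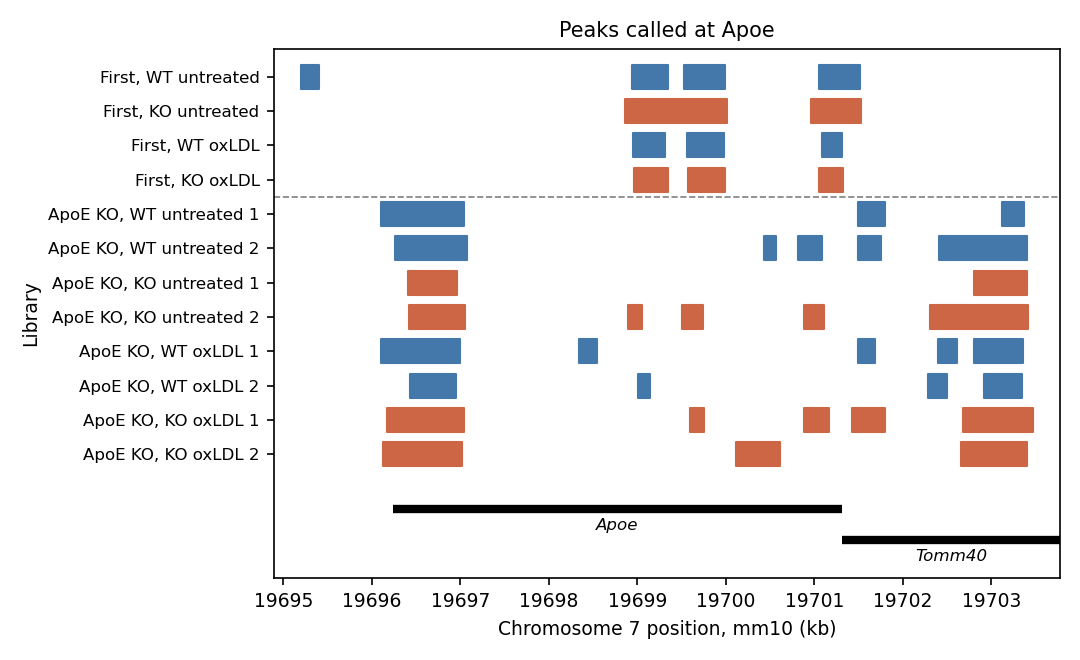
Peaks called at Apoe on chromosome 7 (horizontal axis, mm10 position in kb) in each of the 12 libraries (vertical axis). Blue bars are peaks of WT and orange bars peaks of KO libraries, black bars are genes, and the dashed line parts the cohorts. The 8 ApoE KO libraries share regions at 19696100 to 19697076 and 19702279 to 19703473 that none of the 4 first-cohort libraries has.

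Macrophage genes had gene-boundary peaks at a higher level than the marker lists of other blood lineages, a difference that was not tested. In the first cohort a mean of 96.9% of 32 macrophage identity genes and 100% of 31 lysosome and autophagy genes had a peak within 1 kb of a gene boundary, against 65.1% of all autosomal protein-coding genes. B cell markers had 41.7%, T and NK cell markers 56.9%, neutrophil markers 63.9%, mast cell and basophil markers 33.3%, dendritic cell markers 71.4% and erythroid and megakaryocyte markers 66.7%. Lists of no lineage were as high, with 100% for cell cycle and SWI/SNF genes and 99.3% for mitochondrial biogenesis and dynamics. In the ApoE KO cohort the corresponding means were 88.7% for macrophage identity, 96.0% for lysosome and autophagy, 49.7% for all genes, 5% for B cell, 27.8% for T and NK cell, 26.4% for neutrophil and 10.4% for mast cell and basophil markers. The largest shift between genotypes among the 24 lists, in lists of equal length, was in dendritic cell markers (14 genes), 5.36 points higher in KO (exact permutation p = 0.25, adjusted p = 0.857), and no list passed.

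KO macrophages had more called peaks than WT macrophages. In the first cohort 141441 peaks were called in untreated KO and 108934 in untreated WT, 1.298-fold, and with oxLDL 95901 and 82177, 1.17-fold. In the ApoE KO cohort the means were 38896 ± 7960 (SD, n = 2) in untreated KO and 34184 ± 7240 (SD, n = 2) in untreated WT, 1.14-fold, with overlapping libraries. With oxLDL they were 34762 ± 1170 (SD, n = 2) and 25984 ± 2244 (SD, n = 2), 1.34-fold, and the libraries did not overlap. The mean log2 difference over the strata was 0.30, or 1.23-fold (exact permutation test, two-sided, p = 0.0278). The p rose to between 0.0556 and 0.0833, with differences of 0.25 to 0.33, without any 1 of the 4 first-cohort libraries or of replicate 1 of untreated WT, replicate 1 of untreated KO and replicate 2 of oxLDL WT in the ApoE KO cohort. It was 0.111 in the ApoE KO cohort alone (difference 0.30), where no p under 0.0556 is possible, and 0.0833 without the 3 libraries whose file names carry L001 (difference 0.33), the smallest p that 12 arrangements allow (exact permutation for both). Depth, which is unknown, also sets peak number.

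**Figure D2:**
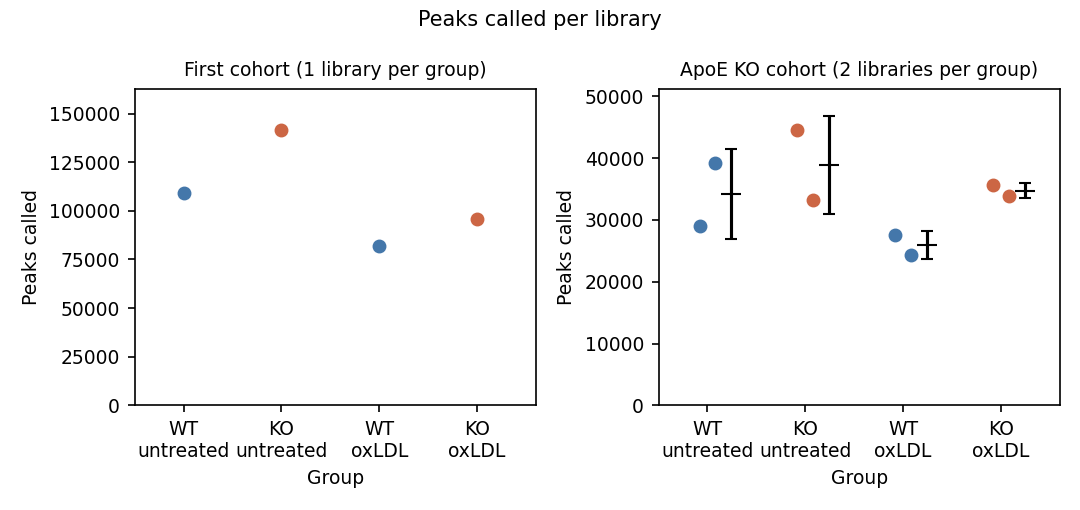
Number of peaks called per library (vertical axis) by group (horizontal axis), first cohort on the left and ApoE KO cohort on the right. Points are libraries, blue for WT and orange for KO, and black marks are mean ± SD of 2 libraries. KO exceeded WT 1.298-fold and 1.17-fold in the first cohort and 1.14-fold and 1.34-fold in the means of the ApoE KO cohort.

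Peaks at gene boundaries made up a smaller share of the KO lists when lists of equal length were compared. In the first cohort the share was 15.2% in untreated KO and 15.8% in untreated WT, and 16.0% and 17.0% with oxLDL. In the ApoE KO cohort it was 32.8% ± 0.0566 (SD, n = 2) in untreated KO and 34.3% ± 0.446 (SD, n = 2) in untreated WT, and 32.8% ± 0.0354 (SD, n = 2) and 34.955% ± 0.997 (SD, n = 2) with oxLDL. Every KO library lay below every WT library of its cohort and treatment. The mean difference was -1.32 points (exact permutation test, two-sided, p = 0.0139, the smallest this design can give). It was -1.82 points in the ApoE KO cohort alone (p = 0.0556, exact permutation, the smallest possible there). Without the 3 libraries whose file names carry L001 it was -1.26 points (p = 0.0833, exact permutation, 12 arrangements), and it was larger in the full lists (-3.23 points) and in the upper part of each list (-2.52 points).

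**Figure D3:**
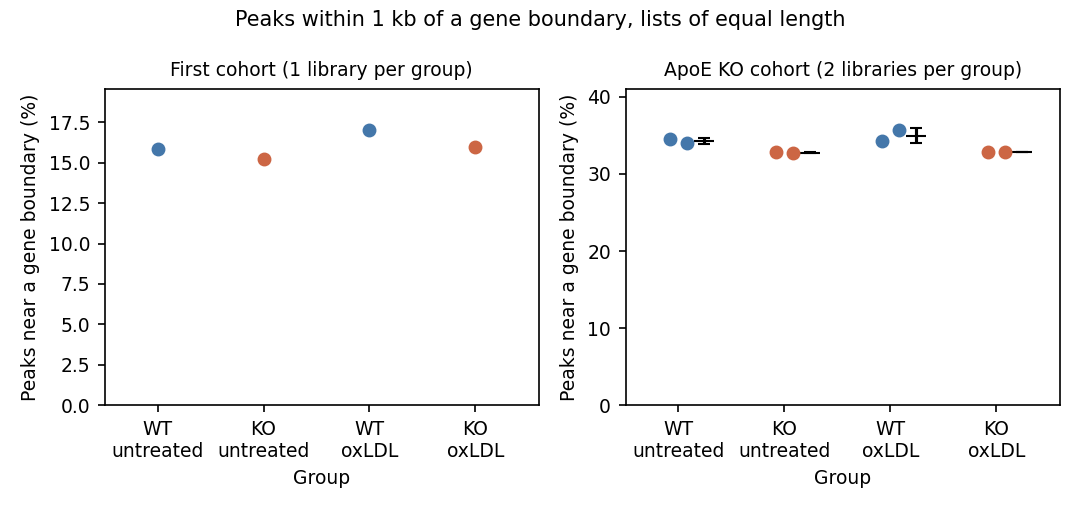
Percent of peaks within 1 kb of a gene boundary in lists of equal length (vertical axis) by group (horizontal axis), first cohort on the left and ApoE KO cohort on the right. Points are libraries, blue for WT and orange for KO, and black marks are mean ± SD of 2 libraries. In each pair the KO libraries lie below the WT libraries, at 15.2% against 15.8% in the untreated first cohort and 32.8% against 34.3% in the untreated ApoE KO cohort.

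Few regions were called in one genotype throughout. A region 413 kb from Cntn3, a neuronal cell adhesion gene (chromosome 6, 102977103 to 102977608), and a region inside Thrb, the thyroid hormone receptor beta gene (chromosome 14, 17863940 to 17864346), were called in 6 of 6 KO and 0 of 6 WT libraries, and no region was called the other way round. With at least 5 of 6 against at most 1 of 6, 55 regions were called in KO and 2 in WT. The KO regions with the highest scores lay inside Hira, a histone chaperone gene (chromosome 16, 18958378 to 18958582), inside Sp110, an interferon-induced gene (chromosome 1, 85604251 to 85604520), 23.6 kb from Tlr2, a receptor for bacterial lipoproteins (chromosome 3, 83865212 to 83865642), inside Thsd1 (chromosome 8, 22228469 to 22229013) and inside Arpp21 (chromosome 9, 112225051 to 112225656). Another region inside Sp110 (chromosome 1, 85605462 to 85605693) was called in all 8 ApoE KO and in 0 of 4 first-cohort libraries. It had 7 other such regions within 1 Mb, so repeated sequence or read filtering cannot be told apart there. A region at Hmox1 (chromosome 8, 75100495 to 75102982), chosen after its values were seen, was called in 5 KO and 1 WT libraries. Hmox1 is the heme oxygenase gene of the antioxidant list. The region's centre lay 1145 bp outside the gene, but with a length of 2488 bp the region overlaps the gene boundary. The WT regions lay 2.9 kb from Ttc12 (chromosome 9, 49488928 to 49489422) and inside Zhx2, a transcriptional repressor gene (chromosome 15, 57705647 to 57706367). In lists of equal length the counts were 0 and 0 for 6 of 6 against 0 of 6, and 7 in KO and 3 in WT for the wider rule. The 2 regions became 7 without the untreated WT library of the first cohort, and 4 without the oxLDL KO library of the first cohort, replicate 2 of untreated KO or replicate 1 of oxLDL KO in the ApoE KO cohort.

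Gene neighbourhoods with fewer peaks in KO outnumbered those with more, but none passed the test. Of 16692 genes, 0 passed an adjusted p of 0.05 in limma, and 1538 had an unadjusted p under 0.05, 1095 with fewer and 443 with more peaks in KO. In the authors' full lists 0 passed and the unadjusted split was 1 with fewer and 3135 with more, since the median of all genes moved to 0.21 on the log2 scale with the longer KO lists. The lower neighbourhoods with the smallest p were those of Ly6g5c (log2 -0.43, SE 0.0549, adjusted p = 0.267), Rbm39, a splicing factor gene (-0.29, SE 0.0395, adjusted p = 0.267), Kdm1a, a histone demethylase gene (-0.26, SE 0.0394, adjusted p = 0.267), and 4 neighbouring histone genes that share their peaks, H3c10, H2ac13, H2bc13 and H2bc14 (-0.47, SE 0.0695, adjusted p = 0.267). The higher ones were those of Elapor2 (0.80, SE 0.121, adjusted p = 0.267), Sema3d, a secreted guidance gene (1.26, SE 0.191, adjusted p = 0.267), Thsd7b (1.198, adjusted p = 0.39), Add2 (1.17, adjusted p = 0.39) and Bzw2 (0.29, adjusted p = 0.39). For Sema3d, Thsd7b and Add2 each of the 4 KO libraries of the ApoE KO cohort had 1 peak and each of the 4 WT libraries 0, so that the pseudocount largely sets their log2 values and tied counts their SE. Elapor2 (2 against 1), Bzw2 (4 against 3) and Rbm39 (4 against 5) likewise had no spread within genotype there. Smarcd1 (-0.28, SE 0.264), Apoe (-0.19, SE 0.138), Nrf1 (-0.20, SE 0.238) and Lyz2 (0.00, SE 0.093) had adjusted p of 0.671 to 1.0. KO against WT gave 0 genes in untreated cells and 0 with oxLDL in limma, with 1149 and 1132 at an unadjusted p under 0.05. Without 1 first-cohort library the count over both treatments was 15 (untreated WT), 7 (untreated KO), 7 (oxLDL WT) or 64 (oxLDL KO). With the ApoE KO cohort alone 423 genes passed over both treatments, 364 of them with no residual spread between replicates, as happens with tied small whole numbers.

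None of the 24 gene lists passed for genotype (lowest adjusted p = 0.294 in camera, and 0.614 with an estimated correlation), and 0 list members passed over all genes, with 3 when adjusted over the list alone. Macrophage identity had 25 of 32 neighbourhoods below 0 (camera adjusted p = 0.294), among them Fcgr1, an IgG receptor gene (log2 -0.20), Ctsb, a lysosomal protease gene (-0.24), and Cd14, the LPS co-receptor gene (-0.22). Cholesterol efflux and LXR genes had 17 of 25 below 0 (camera adjusted p = 0.294), such as Nr1h2, which encodes LXR beta (-0.25), and Cyp27a1, a sterol hydroxylase gene (-0.68). PPAR and lipid handling genes had 20 of 26 below 0 (camera adjusted p = 0.294), such as Plin3 (-0.28) and Angptl4 (-0.32). These members were chosen after their values were seen, and each had an adjusted p of at least 0.428. SWI/SNF subunit genes had 20 of 26 below 0 (adjusted p = 0.469), NF-kB inflammatory genes 23 of 36 (adjusted p = 0.552), and modified LDL uptake genes 12 of 16 (adjusted p = 0.447). The median of all genes was -0.03. These directions turned in the full lists, where the median of all genes was 0.21 and 31 of 32 macrophage identity, 19 of 25 cholesterol efflux and LXR, 20 of 27 PPAR and lipid handling, 25 of 26 SWI/SNF, 32 of 36 NF-kB and 16 of 17 modified LDL uptake genes were above 0, and none of these lists passed (camera adjusted p of 0.556 to 0.829).

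Fewer peaks were called with oxLDL, at a p just above the threshold. In the first cohort oxLDL lists were 0.754-fold the untreated ones in WT and 0.678-fold in KO. In the ApoE KO cohort they were 0.760-fold in WT and 0.894-fold in KO, where the KO libraries overlapped. Treated and untreated WT libraries of the ApoE KO cohort also differ in the file-name mark throughout. The mean log2 difference was -0.37 or 0.772-fold (exact permutation test, two-sided, p = 0.0556), and -0.44 in covered base pairs (p = 0.0417, exact permutation). It was -0.26 in the ApoE KO cohort alone (p = 0.222) and -0.38 without the 3 L001 libraries (p = 0.25, exact permutation for both). Leaving out single libraries gave -0.43 without replicate 1 of untreated WT (p = 0.0417) or replicate 2 of untreated KO (p = 0.0139) in the ApoE KO cohort, and -0.31 without either KO library of the first cohort (p = 0.111, exact permutation for all). The gene-boundary share in lists of equal length differed by 0.679 points (p = 0.0972, exact permutation), from 15.5% untreated to 16.5% with oxLDL in the first cohort and from 33.5% ± 0.915 to 33.9% ± 1.35 (SD, n = 4) in the ApoE KO cohort. In the full lists it was 3.44 points higher with oxLDL (p = 0.0278, exact permutation), and in the upper part of each list it was -0.0563 points (p = 0.931). Without ApoE KO WT oxLDL replicate 1 it was 0.855 points (p = 0.0139, exact permutation).

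No region was called in all 6 oxLDL libraries and 0 of 6 untreated libraries, or the other way round. At the stricter threshold 14 regions were called in all 6 untreated and 0 of 6 oxLDL libraries. With at least 5 of 6 against at most 1 of 6, 58 regions were called without oxLDL and 0 with it. The untreated regions with the highest scores lay inside Gng12, a G protein subunit gene (chromosome 6, 66962346 to 66962859), 152 kb from Mrps30 (chromosome 13, 118538728 to 118539211), 69.3 kb from Dscam (chromosome 16, 97240036 to 97240732), inside Anks1b (chromosome 10, 90380049 to 90380605) and 1.32 kb from Cxcl1, a neutrophil-attracting chemokine gene of the NF-kB list (chromosome 5, 90894253 to 90894632). In lists of equal length the direction turned, with 15 regions called with oxLDL and 4 without. The count of regions called in all untreated and 0 oxLDL libraries was 6 without replicate 1 and 4 without replicate 2 of untreated WT, 5 without replicate 2 of untreated KO in the ApoE KO cohort, and 1 without the oxLDL KO library of the first cohort.

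Gene neighbourhoods with oxLDL gave 0 of 16692 genes past an adjusted p of 0.05 in limma, with 1089 at an unadjusted p under 0.05, 610 higher and 479 lower. In the full lists the unadjusted split was 2 higher and 4808 lower, and the median of all genes moved to -0.27. The higher neighbourhoods with the smallest p were those of Epha7 (log2 0.61, SE 0.101), Pecr (0.23, SE 0.0401), Klrb1a (0.65, SE 0.12), Clec4n, a C-type lectin receptor gene (0.31, SE 0.0606), and Sstr4 (0.54, SE 0.104). The lower ones were those of the chemokine gene Ccl25 (-0.33, SE 0.0437), Herpud2 (-0.41, SE 0.0594), Kdm1a (-0.26, SE 0.0394), Pemt, which makes phosphatidylcholine (-0.43, SE 0.0719), and Acyp1 (-0.37, SE 0.0697). All 10 had an adjusted p of 0.633. In the ApoE KO cohort Pecr (7 peaks against 6), Ccl25 (3 against 4) and Acyp1 (2 against 3) had no spread within a treatment, so tied counts largely set their SE. Kdm1a had the same values here as for genotype. In the ApoE KO cohort every untreated and every WT library had 3 peaks near Kdm1a. Both lower means there (2.5) therefore come from the KO libraries with oxLDL. Smarcd1 (-0.03), Apoe (0.09), Nrf1 (-0.10) and Lyz2 (0.14) had adjusted p of 0.765 to 1.0. None of the 24 lists passed (lowest adjusted p = 0.621). PPAR and lipid handling had 18 of 26 neighbourhoods above 0 (adjusted p = 0.621), cholesterol efflux and LXR 16 of 25 (adjusted p = 0.636), and NF-kB inflammatory genes 17 of 36 (adjusted p = 0.679). These counts fell to 3 of 27, 0 of 25 and 0 of 36 in the full lists (camera adjusted p = 0.907 for each), with the lower median of all genes. Of list members 0 passed over all genes and 2 when adjusted over the list alone. OxLDL gave 0 genes in WT and 0 in KO in limma, with 972 and 826 at an unadjusted p under 0.05. Without 1 library the count over both genotypes was 15 (untreated WT), 5 (untreated KO), 7 (oxLDL WT) or 28 (oxLDL KO) in the first cohort and 1 for replicate 1 of untreated WT in the ApoE KO cohort. With the ApoE KO cohort alone 373 genes passed over both genotypes, 353 of them with no residual spread.

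The genotype difference was not shown to depend on oxLDL. The log2 difference in peak number between KO and WT was 0.22 with oxLDL and 0.38 without in the first cohort, and 0.42 and 0.19 in the ApoE KO cohort, opposite directions. The pooled interaction was 0.040 (exact permutation test, two-sided, p = 0.931). It was -0.086 in covered base pairs, and without replicate 2 of untreated WT, untreated KO or oxLDL WT in the ApoE KO cohort it was -0.068, -0.065 and -0.0037. No gene neighbourhood passed for the interaction in limma (662 at an unadjusted p under 0.05), and no gene list did (lowest adjusted p = 0.386). NF-kB inflammatory genes had 26 of 36 neighbourhoods above 0 and oxidative phosphorylation genes 25 of 43 below 0 (adjusted p = 0.386 for both), and in the full lists 26 of 36 and 24 of 43 were above 0. NRF2 antioxidant genes, which include Hmox1, had 15 of 22 neighbourhoods above 0 (adjusted p = 0.744).

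Peak sets overlapped widely across groups. In lists of equal length the Jaccard index between libraries ran from 0.642 to 0.778 in the first cohort and from 0.502 to 0.638 in the ApoE KO cohort, and the 4 replicate pairs lay between 0.589 and 0.633. In the full lists the index within a treatment minus that between treatments was 0.0552, against a median of 0.00931 over the 72 splits (p = 0.0556, exact permutation, one-sided for a higher value). It was 0.0427 in lists of equal length (p = 0.0278, exact permutation), and 0.0125 in the full lists without any 1 of the 4 first-cohort libraries (p = 0.111, exact permutation). The last value was the same whichever of the 4 was left out, so these runs count as 1. The index within a genotype was lower than that between genotypes, by a difference of -0.00942, against a median of -0.0240 over the splits (p = 0.0556, exact permutation, one-sided for a higher value). With equal list lengths this difference was -0.00567 against a median of -0.0182 (p = 0.0278, exact permutation), and in the full lists it was 0.0180 without any 1 of the 4 first-cohort libraries (p = 0.111, exact permutation). Here too the last value was the same whichever of the 4 was left out.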

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

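The tests of the file-name mark, list length, depth and genome-wide spread below, and the counts over other splits of the samples, were chosen after the results were seen.

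The median peak width of WT libraries moved in opposite directions with oxLDL in the cohorts. In the first cohort it was 382 bp with oxLDL and 394 bp without, a difference of -12 bp. In the ApoE KO cohort the means were 376.5 bp and 360.5 bp, a difference of 16 bp. In KO libraries the width was lower with oxLDL in both cohorts. It was 384 bp against 404 bp in the first cohort. In the ApoE KO cohort the means were 359.75 bp against 419.5 bp, with overlapping libraries. The difference between the cohorts in WT was not tested. In the ApoE KO cohort both untreated WT libraries carry L001 in the file name and both oxLDL WT libraries carry L003. Libraries with L001 had median widths of 300 to 364 bp and those with L003 371 to 458 bp. The file-name mark and oxLDL therefore cannot be told apart in WT there.

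The gene-boundary share was lower in KO in lists of equal length. Longer lists had a lower share, by -1.60 points per doubling of peak number. With peak number as a covariate the KO difference was -0.999 points (permutation of genotype labels over all arrangements, p = 0.0139, the smallest this design can give). Labels moved while peak numbers stayed fixed, and peak number differed between genotypes, so this p is approximate. That slope is poorly known. Share and peak number correlated at -0.76 over the 8 ApoE KO libraries (Pearson r), and at -0.49 without the 2 most extreme peak numbers. Of 4 pairs within a cohort whose KO list was no longer than the WT list, 3 had the lower share in KO. All 3 use the same WT library, replicate 2 of untreated WT in the ApoE KO cohort. The pairs were not matched for treatment, so they are not separate checks. The covariate therefore argues against list length as the whole cause only as far as this slope holds. The file-name mark, which is not stated to be a lane, cannot be told apart from genotype in untreated ApoE KO cells, and without the 3 libraries that carry L001 the difference was -1.26 points with 12 arrangements, too few for a p under 0.0833. Depth, which is unknown, and the Baf60a genotype itself stay among the open explanations, as untested.

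Regions called in KO outnumbered those called in WT, 55 against 2. In lists of equal length 70% of the separated regions were on the KO side, against 96.5% in the full lists, consistent with list length as a source of the excess. The stricter threshold gave a log2 difference in peak number of 0.33, but in the first cohort it takes 50% of each list and cannot change the ratio, and reads per library are unknown, so depth cannot be told apart from genotype. Of the 72 splits of the samples 2 gave as many as the real 57 regions, and the highest other, 61, exchanged untreated WT replicate 2 with untreated KO replicate 2 of the ApoE KO cohort. In lists of equal length 7 of 72 splits gave as many as the real 10 (highest other 12), so chance is not excluded there.

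The regions beside Apoe were called in all 8 ApoE KO libraries and in 0 of 4 first-cohort libraries. Only 56 of the 17495 regions called in all 8 libraries (0.32%) were called in 0 of 4, and 2 of these lay within 2 kb of Apoe (exact hypergeometric test, one-sided, p = 1.01e-05). That p counts neighbouring regions, already seen to differ, as independent draws, so it does not exclude a cohort difference spread over the genome. Of the 56 regions, 44 had another within 1 Mb. The 2 at Apoe are among these only because each lies beside the other, so the count does not bear on Apoe itself. Repeated sequence or read filtering cannot be told apart there without a genome. The engineered Apoe allele is a candidate explanation that stays open, since protocol and peak caller differ between the cohorts and the labels do not give the ApoE status of the first.

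For genotype, 1 of 72 splits gave the real 2 regions called in 6 of 6 against 0 of 6 (highest other 1). At the stricter threshold 2 of 72 splits gave as many as the real 4, and the highest other gave 9. The real count in the ApoE KO cohort alone was 287 and the highest other 437, with 18 splits, too few for a share under 0.05. For treatment at 5 of 6 against 1 of 6, 1 of 72 splits gave the real 58 (highest other 53), and in lists of equal length 1 of 72 gave the real 19 (highest other 18), and 1 of 72 gave the real 14 at 6 of 6 against 0 of 6 with the stricter threshold (highest other 11). The highest others lie close to the real counts and the directions are opposite, 58 without oxLDL in full lists and 15 with it against 4 without in lists of equal length, so little rests on these ranks. Where the real count is 0 every split gives as many, which says nothing on chance: 72 of 72 for treatment regions at 6 of 6 against 0 of 6 (highest other 3), and for genes past the threshold in limma 72 of 72 for genotype (highest other 0) and for oxLDL (highest other 3). Within a treatment or genotype the 6 splits are also too few, with a real count of 0 and a highest other of 1 for genotype in untreated cells, 0 with oxLDL, 8 for oxLDL in WT and 0 in KO. At an unadjusted p under 0.05, the real 1538 genes for genotype were reached by 1 of 72 splits (highest other 1273, median of the others 586), and the real 1089 for oxLDL by 2 of 72 (highest other 1206).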

How the results depend on the processing

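Leaving out the 3 libraries of L001, the peak number covariate and the estimated correlation in full lists were chosen after seeing the data, and the other alternatives before. The lower gene-boundary share of KO kept its direction in 7 of 7 alternatives and in all 12 leave-one-out runs (-1.56 to -1.14 points). Every KO library lay below every WT library of its cohort and treatment. Runs that only leave out libraries or add the replicate block therefore could not turn the direction. Leaving out either first-cohort library of a treatment gave the same run, here and for the KO difference in peak number. The size of the share difference moved, to -3.23 in full lists and -2.52 in the upper part of each list. Its exact permutation p was above 0.05 in the ApoE KO cohort alone (-1.82) and without the L001 libraries (-1.26), where no smaller p is possible. The log2 KO difference in peak number did not pass in the ApoE KO cohort alone (0.30), with the replicate block (0.30) or without the L001 libraries (0.33), where no p under 0.0833 is possible, nor under 0.0556 in the ApoE KO cohort alone, and ran from 0.25 to 0.36 without single libraries. With oxLDL, peak number passed as covered base pairs (-0.44) and ran from -0.43 to -0.31 without single libraries. The interaction turned with covered base pairs (-0.086) and ran from -0.068 to 0.23. The oxLDL difference in gene-boundary share was 3.44 points in full lists and -0.0563 in the upper part of each list, and ran from 0.502 to 0.855. Regions called in 6 KO and 0 WT libraries numbered 4 with the stricter threshold, 0 in lists of equal length, 1 with 50% coverage, 282 in the ApoE KO cohort alone (5 for WT), 55 with the wider rule (2 for WT) and 7940 in the L003 oxLDL libraries (495 for WT), where 1 KO library stands against 2 WT libraries and the unequal numbers largely set the counts, and 2 to 7 without single libraries (0 for WT). Regions called without oxLDL numbered 14 with the stricter threshold, 1 with 50% coverage, 238 in the ApoE KO cohort alone (1 with oxLDL) and 58 with the wider rule, and 0 to 6 without single libraries (0 with oxLDL). Genes past the threshold in limma, 0 in the full design, numbered 423, 207 and 319 in the ApoE KO cohort alone for genotype over both treatments, untreated and with oxLDL, 373, 230 and 236 for oxLDL over both genotypes, in WT and in KO, and 359 for the interaction. Of these 364, 186, 288, 353, 212, 226 and 343 had no residual spread, and for genotype over both treatments and oxLDL over both genotypes the real counts were reached by 1 of 18 splits of that cohort (highest other 359 for each); splits were not run for the other contrasts. Without single libraries the counts ran from 0 to 64, 28, 88, 28, 30, 61 and 24 in that order, the highest of each without the oxLDL KO or the untreated WT library of the first cohort. In full lists 1 gene list passed, NRF2 antioxidant for genotype with oxLDL (adjusted p = 0.0295, median 0.33 against 0.25 for all genes), a call lost with an estimated correlation (adjusted p = 0.962) and in lists of equal length (adjusted p = 0.528). Overlap within minus between genotypes was -0.00567 in lists of equal length and ran from -0.0153 to 0.0180, and that for treatment was 0.0427 and ran from 0.0125 to 0.0619. The cause was not tested for these changes. Replicate numbers did not pair the samples (6 correlations of -0.09 to 0.04), and the replicate block ended only the call on peak number, with 64 arrangements. Motif shares were not run, for want of a genome. Depth is unknown and limits every comparison of peak number.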

Other observations

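The location classes below were tested after the gene-boundary result was seen. In lists of equal length KO libraries had a larger share of peaks far from genes. Because the 5 classes divide each whole list, the lower gene-boundary share forces a higher share elsewhere. The values below show where that share went and are not separate evidence. The adjusted p counts the gene-boundary class among the 5. Peaks over 50 kb outside genes made up 8.74% ± 0.119 of KO and 7.92% ± 0.205 of WT lists in the ApoE KO cohort (SD, n = 4), and 9.93% and 9.25% in the first cohort, a mean difference of 0.747 points (exact permutation p = 0.0139, adjusted p = 0.0232 over 5 classes). Peaks 10 to 50 kb outside genes differed by 0.333 points (exact permutation p = 0.0139, adjusted p = 0.0232). Peaks inside genes differed by 0.407 points (exact permutation p = 0.0833) and those 1 to 10 kb outside by -0.165 points (exact permutation p = 0.319). The 55 KO regions lay within 1 kb of a gene boundary in 6 cases, 10.9% against 8.59% of 17580 background regions (Fisher's exact p = 0.471). The background is a part of the 147937 merged regions, and these are shares of regions, not of the peaks of a list.

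Markers of other lineages had few gene-boundary peaks in the ApoE KO cohort, with 20.8% of stromal and endothelial, 34.2% of erythroid and megakaryocyte and 36.6% of dendritic cell markers, against 49.7% of all genes. The first-cohort values were 54.2%, 66.7% and 71.4%, against 65.1%. Chosen after their values were seen, a region inside Lef1, a transcription factor gene (chromosome 3, 131139291 to 131140096), was called in 6 KO and 1 WT libraries, and a region outside Pdgfra, a growth factor receptor gene (chromosome 5, 75207959 to 75208534), in 5 KO and 0 WT libraries. A region 27.9 kb from Anxa1, an annexin gene (chromosome 19, 20345010 to 20345960), was called in 5 untreated and 1 oxLDL libraries.

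Gene by gene, the cohorts had little in common. Across 15609 genes, which are not independent replicates, the correlation of log2 differences between the cohorts was 0.107 for genotype and 0.037 for oxLDL.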
